A study of Mus musculus with 2 samples.

How the data were processed

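Chromatin immunoprecipitated with an antibody against Tbx3 and non-precipitated input DNA, both from mouse embryonic stem cells, were sequenced as 1 library each. Per the labels' protocols, cells of the D3 and R1 lines were grown on inactivated feeder fibroblasts with leukaemia inhibitory factor and received no treatment; the labels do not say which line gave which library. Per the same protocols, sonicated chromatin was precipitated, adapters were ligated, and the libraries were amplified by PCR, cut from an agarose gel and sequenced on an Illumina Genome Analyzer. No molecular identifiers are described.

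The deposited files analysed here hold 1 line per mapped tag. Positions refer to the mouse build mm8, per the submitters' processing notes, and the highest tag positions of the 2 files lay within 7174 bp of each other on every shared chromosome. The aligner, its settings and the filters are not given in the sources used here. For the ChIP library the deposited file gives a chromosome, a position and a strand. No position and strand occurred more than once in it, so repeated tags had been collapsed before deposit, and the name given to the list speaks of unique hits. For the input the deposited file gives the lower and upper end of each 35 bp tag, with repeats kept. A correlation between the strands at a shift of 33 bp in the ChIP tags showed that their listed position is the 5′ end; input 5′ ends were taken from the lower end on the plus strand and the upper end on the minus strand. The deposited positions could be offset by a base between the files, which is immaterial on the 100 bp grid used below.

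The scan, its threshold and most of its alternatives were fixed before the data were examined. Tags were collapsed to 1 per position and strand. Each tag was moved by 62 bp towards its 3′ end, which is the fragment length from the strand cross-correlation of the ChIP tags (125 bp, highest point of an 11 bp running mean at shifts from 60 bp) divided by 2 and rounded down. Windows of 300 bp were placed every 100 bp on the 20 chromosomes covered by both libraries (1 to 19 and X). The ChIP tag count of each window was compared by a one-sided exact Poisson test with a local rate. That rate was the largest of the genome-wide ChIP rate and the input rates in 1 kb, 5 kb and 10 kb around the window, each widened by 100 bp to centre it, with input scaled by 0.689, the ratio of collapsed tag totals. Benjamini-Hochberg adjustment ran over the 20081495 windows with a tag in either library, and windows with an adjusted p under 0.05 were merged where they overlapped or touched. A region is described by its window of smallest p, called its top window. With 1 library per group the test compares these libraries and not the conditions, and there is no measure of the spread between cultures. Intervals are 95% exact Poisson or exact (Clopper-Pearson) binomial intervals and cover counting error only, since there is 1 library per group. Those of an enrichment divide the limits of the ChIP count by a local rate taken as fixed. They leave out the counting error of the input and are therefore too narrow.

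The scan was tested on simulated tags drawn at the depths of both libraries from the input's rates in 10 kb bins. It called 0 regions without planted signal. Both simulated libraries came from the same rates, with tags spread evenly within each 10 kb bin and no difference in filtering. The 0 therefore does not measure false calls in the real tags, where input tested against input gave 46 regions. Of 50 planted regions per level, the scan found 25 at a mean of 8 extra tags, 39 at 12, 50 at 20 and 49 at 40. Of the 170 calls, 7 lay away from any planted region. Regions with weak enrichment are therefore under-called at this depth.

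Strand cross-correlation was the Pearson correlation of plus-strand and shifted minus-strand 5′ ends, presence or absence per base, averaged over chromosomes with tag weights, for shifts of 0 to 400 bp; with repeated tags kept, the number of tags per base was used in place of presence or absence. The normalised strand coefficient was the smoothed correlation at 125 bp over the lowest smoothed value, and the relative strand coefficient was the rise at 125 bp over the rise at the read-length shift. A region's strand offset was the median minus-strand 5′ end less the median plus-strand 5′ end within 200 bp of its top window, where each strand had at least 3 tags. Because moving tags by 62 bp favours an offset of 124 bp in called regions, offsets and strand profiles were taken from a scan of unmoved tags, which favours an offset of 0 instead and was added after seeing the data. Covered length was the number of 1 kb bins with a tag in either library. For long stretches, log2 ratios of ChIP to scaled input tags were taken in 1 Mb bins holding more than 30% of the chromosome's median in both libraries, and were split by recursive segmentation with at least 5 bins per stretch; this step was added after the tag totals by chromosome had been seen. Regions were also divided, after their values were seen, by whether the top window held at least 10 input tags. The regions named in the text are the 20 with the smallest adjusted p, a rule fixed beforehand for the case that genes cannot be placed, and the chromosome 6 and 8 stretches were chosen after their values were seen. Exchanging the libraries had been meant to give an empirical false discovery rate, and its outcome is given with the results.

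Planned comparisons with transcription start sites, gene lists and sequence motifs were not made, because no genome or annotation of mm8 was used here and coordinates were not converted between builds. Chromosomes Y and M were left out of the scan because the input tags analysed here cover chromosomes 1 to 19 and X. Other settings covered repeated tags, window width, the local rate, input scaling and depth, the threshold, the tag shift and random subsets of the ChIP tags. Calculations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9.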

Results

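To look for binding sites of Tbx3, a T-box transcription factor, chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in mouse embryonic stem cells. The comparison asked where DNA recovered with the Tbx3 antibody was enriched over input, which is sheared chromatin sequenced without precipitation. The Tbx3 ChIP library held 6885523 tags, each at a different position and strand. The input library held 10647721 tags, of which 9982870 were distinct and 664851 (6.24%) repeated a position and strand already seen. Plus-strand tags made up 49.97% of the ChIP and 49.91% of the input tags. On the 20 chromosomes compared, 6881110 ChIP and 9982870 distinct input tags entered the scan, so an average 300 bp window held 0.853 ChIP tags. There was no second library of either kind, so no value below has a replicate error.

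With tags collapsed to 1 per position and strand, the ChIP library had a second maximum in the correlation between strands, at a fragment-length shift, and the input did not. In the ChIP library, the correlation between strands fell to 0.000658 at a shift of 72 bp and rose again to 0.00110 at 125 bp. In the input, it was 0.00130 at 72 bp and 0.00122 at 125 bp, and the smoothed curve rose by no more than 3.37e-05 anywhere after 72 bp, against 0.000444 in ChIP. Read at 125 bp, the normalised strand coefficient was 2.87 for ChIP and 1.42 for input, and the relative strand coefficient was 0.686 and 0.213. The order of the normalised coefficients depended on collapsing: with repeated tags kept and counted at each base, that of the input was 4.56, above the ChIP value. Both libraries had a sharp maximum near the length of a tag, at 33 bp in ChIP and 32 bp in input. That read-length maximum remained higher than the fragment maximum in the ChIP library, at 0.00143 against 0.00110.

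**Figure D1:**
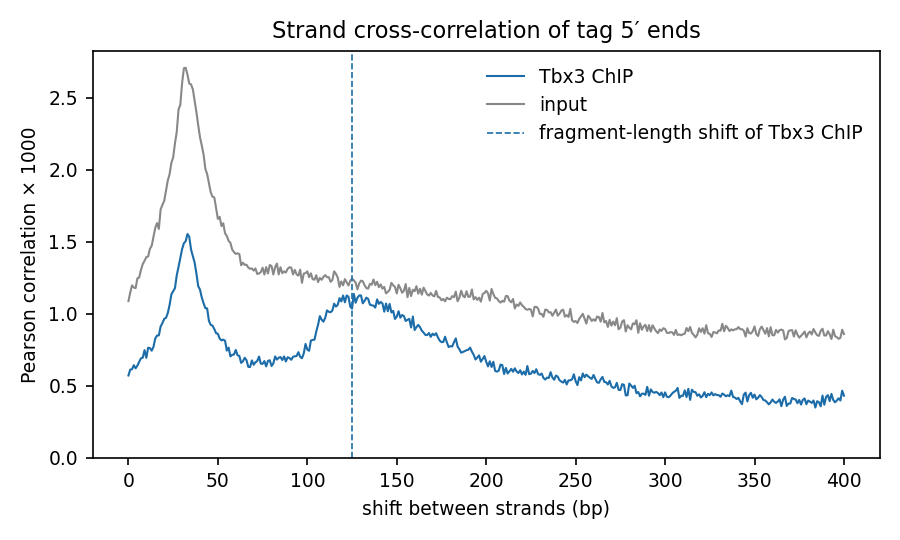
Pearson correlation (multiplied by 1000) between plus-strand and minus-strand tag 5′ ends, on the vertical axis, against the shift between strands in bp, for 1 Tbx3 ChIP and 1 input library. Both curves peak near 33 bp, and only the ChIP curve has a second maximum, at the dashed line at 125 bp.

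Across the genome, 1147 regions were enriched in the Tbx3 ChIP over input (one-sided exact Poisson test, Benjamini-Hochberg adjusted p under 0.05), together covering 472.7 kb. The regions were short and mostly modest in tag number. Their median width was 400 bp (interquartile range 300 to 500 bp, longest 1500 bp). Their top windows held a median of 11 ChIP tags (interquartile range 9 to 16, lowest 8), 9.37 times the local rate at the median (interquartile range 7.98 to 11.3). Of the 1147, 1094 had fewer than 10 input tags in the top window, and these had a median enrichment of 9.37 and a median of 1 input tag. The other 53 lay where input tags were piled up as well, with a median of 100 input and 73 ChIP tags per 300 bp and a median enrichment of 2.78. That enrichment is over input averaged over 1 kb or more (median local rate 25.9), and not over the input of the same window. The number of regions depended on the local rate and the threshold: it was 6580 with the genome-wide ChIP rate alone, 1774 with input in 10 kb and the genome-wide rate, and 748 at an adjusted p under 0.01.

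Minus-strand tags lay downstream of plus-strand tags in most regions. Moving tags before calling favours an offset of 124 bp in any called cluster, so offsets were read from regions called on unmoved tags, where calling favours offsets near 0 and neither sign, so the values may be low; this setting was chosen after seeing the data. It called 945 regions, 891 of them with few input tags, and overlapped 821 of the 1147. In the 835 of these 891 with at least 3 tags on each strand the median offset was 107.5 bp (interquartile range 48.8 to 148 bp), and it was above 0 in 732 (87.7%, 95% exact binomial interval 85.2% to 89.8%). The median was 107.5 bp in the regions enriched under 8-fold, with 93.7% above 0 (89.2% to 96.7%), 97 bp in those enriched 8- to 12-fold, with 81.9% above 0 (78.0% to 85.3%), and 130.5 bp in the 59 regions enriched at least 20-fold, with 98.3% above 0 (90.9% to 99.96%). In the 54 regions with many input tags the median offset was 33 bp (interquartile range 24.8 to 37.4 bp), near the read-length shift. It was above 0 in 48 of them (88.9%, 77.4% to 95.8%). The sign alone therefore does not separate them from the regions with few input tags. Over 890 regions with few input tags, leaving out the X-chromosome region of most tags, plus-strand ends were most frequent 50 bp before and minus-strand ends 70 bp after the window centre, at 0.715 tags per region per 20 bp each. Input gave 0.0719 and 0.0584 at the same places.

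**Figure D2:**
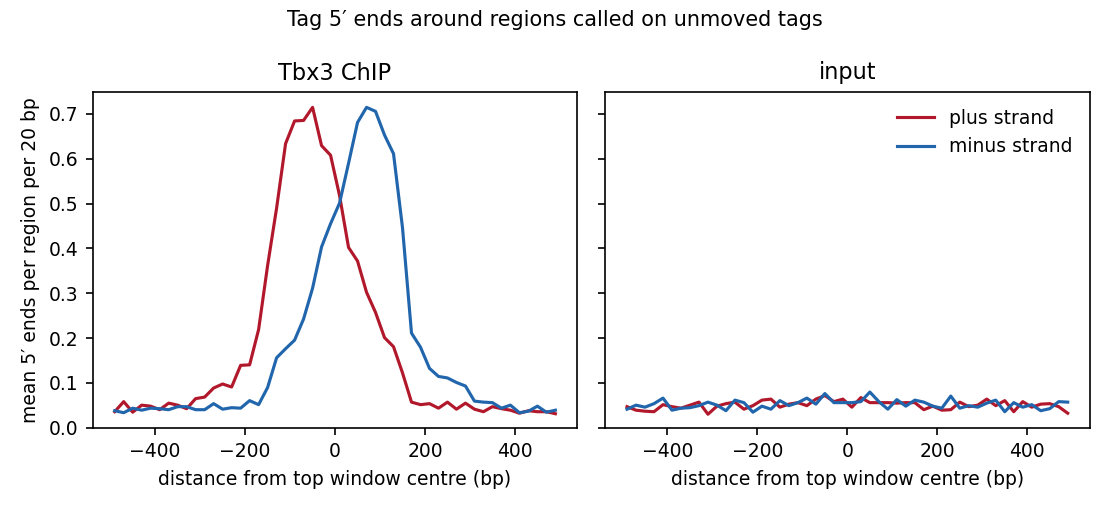
Mean number of tag 5′ ends per region per 20 bp (vertical axis) against the distance in bp from the centre of the top window (horizontal axis), for plus and minus strands, in Tbx3 ChIP (left) and input (right), over 890 regions with fewer than 10 input tags called on unmoved tags. Each strand reaches 0.715 in ChIP, plus 50 bp before and minus 70 bp after the centre, while input holds 0.0719 and 0.0584 there; the regions were called on the same tags, which sets the height, and the calling favoured offsets near 0.

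The strongest sites with few input tags were intervals of 600 to 1000 bp spread over 13 chromosomes (mm8 coordinates; genes at these positions were not analysed here). The 20 regions with the smallest adjusted p (none above 4.83e-38, exact Poisson test with Benjamini-Hochberg adjustment) included 18 with fewer than 10 input tags, whose enrichment ran from 27.2-fold to 164-fold. The region of most tags among these, on chromosome X from 102389201 to 102390200, held 216 ChIP tags in its top window against a local rate of 1.32, an enrichment of 164 (95% interval 143 to 188). The intervals given here take the local rate as fixed. With the input thinned to the ChIP library's number of collapsed tags, the enrichment of this region was 132, outside its interval. The strand offset of the region was 29 bp, against a median of 140.75 bp in the 18. Next came chromosome 2 from 44347201 to 44347900, with 79 tags and an enrichment of 59.0 (46.7 to 73.6) and an offset of 135 bp. A second region of chromosome 2, from 120961701 to 120962500, was enriched 55.7-fold (43.0 to 71.0). Chromosome 11 from 66782501 to 66783200 was enriched 45.9-fold (35.7 to 58.1), and chromosome 18 from 65247701 to 65248400 was enriched 44.6-fold (34.5 to 56.6). The intervals of these last 4 regions overlapped, so their order by enrichment is not resolved by the tag counts. The enrichments also depended on the window: at 600 bp, 18 of the 20 were over 1.5 times lower, the X-chromosome region stood at 104, and the first and second regions of chromosome 2 stood at 32.5 and 37.6, in the opposite order.

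The remaining strong sites lay between 27.2- and 44.2-fold over the local rate. Chromosome 3 from 28063501 to 28064200 was enriched 44.2-fold, chromosome 2 from 159109701 to 159110400 was enriched 43.4-fold, and chromosome 6 from 97013801 to 97014400 was enriched 42.5-fold. Chromosome 17 from 35113501 to 35114300 was enriched 39.7-fold, chromosome 4 from 57376501 to 57377100 was enriched 37.8-fold, and chromosome 9 from 31725601 to 31726300 was enriched 36.5-fold. Chromosome 7 from 130055601 to 130056300 stood at 33.1-fold, chromosome 2 from 33459301 to 33459900 at 31.9-fold, and chromosome 8 from 108856001 to 108856700 at 31.0-fold. Chromosome 1 from 183999401 to 184000000 stood at 29.0-fold and chromosome 6 from 124794301 to 124795000 at 27.2-fold. On chromosome 12, 2 regions lay 300 bp apart, from 99699801 to 99700400 (30.1-fold) and from 99700701 to 99701400 (32.1-fold), and with windows of 600 bp both had the same value of 17.7-fold, so they may be 1 site. The other 2 of the 20 coincided with input pile-ups: chromosome 9 from 35054701 to 35055300, with 279 ChIP and 296 input tags (4.40-fold), and chromosome 2 from 98464501 to 98465000, with 268 ChIP and 348 input tags (3.09-fold). Their local rates of 63.4 and 86.7 averaged input over 1 kb or more, so these enrichments are not over the input of the same window. Their strand offsets were 33.5 and 34 bp. With repeated input tags kept, ChIP lay below the local rate in both, at 0.281 and 0.0662 times it, so neither is an enrichment that holds across the handling of repeats; the ChIP tags had been collapsed before deposit.

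**Figure D3:**
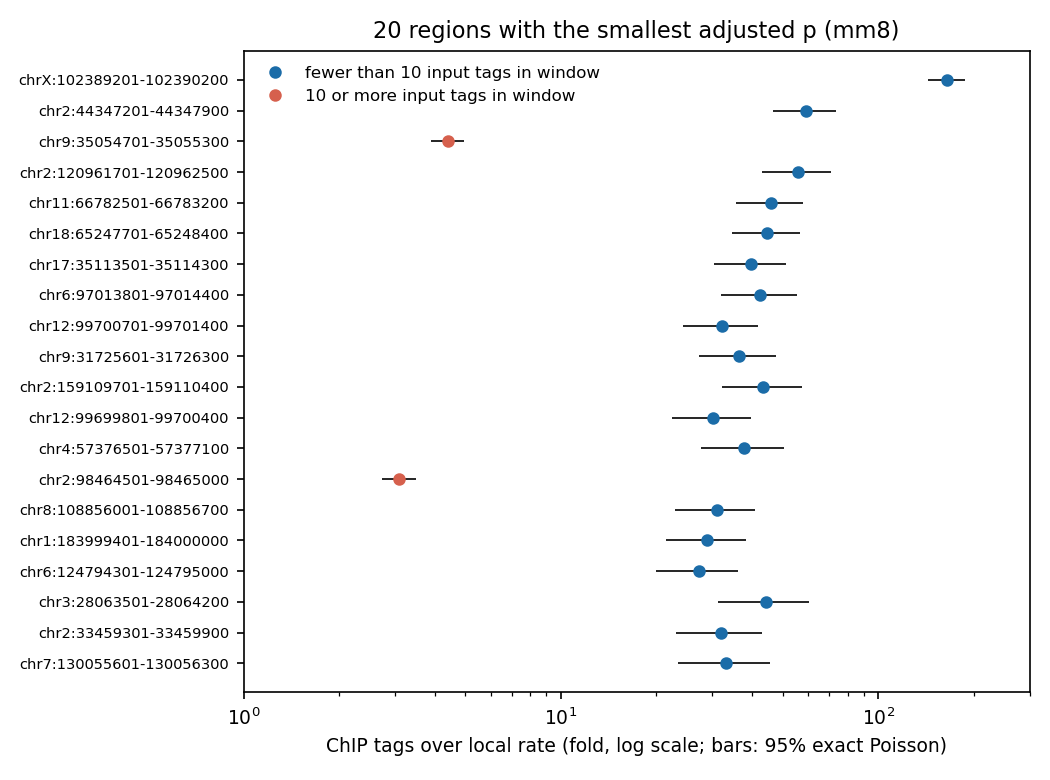
Enrichment of the ChIP tag count over the local rate (horizontal axis, fold, log scale) for the 20 regions with the smallest adjusted p, listed by mm8 coordinates on the vertical axis, with 95% exact Poisson intervals of the ChIP count. The X-chromosome region stands apart at 164-fold, 17 others with few input tags lie between 27.2- and 59.0-fold, and the 2 with 10 or more input tags lie at 3.09- and 4.40-fold.

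Few of the precipitated tags fell in enriched regions. The regions held 21782 of 6881110 ChIP tags, a share of 0.317% (95% exact binomial interval 0.312% to 0.321%), against 9557 of 9982870 input tags, 0.0957% (0.0938% to 0.0977%). In the 1094 regions with few input tags the shares were 0.241% (0.237% to 0.244%) and 0.0256% (0.0246% to 0.0266%), a ratio of 9.41. In the 53 regions with many input tags they were 0.0760% and 0.0702%, a ratio of 1.08. The regions were called on the same tags, so these shares describe the libraries and are not an independent test.

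The scan was also run with the libraries exchanged and within the input. With input tested against ChIP, 2806 regions were called, more than in the forward direction. This exchange had been planned as an empirical false discovery rate, and read that way it would exceed all 1147 forward calls. The planned check thus failed, and the Tbx3 regions have no usable empirical false discovery rate. Of those 2806, 1672 contained 0 ChIP tags. The input was the deeper library, and with thinned input 1826 regions were called, still more than in the forward direction. When the input tags were divided at random into 2 subsets and one was tested against the other, 46 regions were called, 40 of them at input pile-ups and 6 elsewhere. Random subsets of the ChIP tags, of 3441605 and 3439505 tags, gave 412 and 414 regions against input, and 212 were found in both (51.5% and 51.2%). The median of 11 ChIP tags per top window lay close to 8, the lowest count called.

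Enriched regions were unevenly spread over chromosomes, with chromosomes 8 and 11 highest and X lowest. The genome-wide rate was 0.474 regions per covered Mb. Chromosome 8 carried 103 regions (0.856 per Mb, 95% exact Poisson interval 0.699 to 1.04), chromosome 11 carried 87 (0.753, 0.603 to 0.929), and chromosome X carried 26 (0.192, 0.126 to 0.282). Tags on X were sparse in both libraries, at 0.472 of the autosome median density in ChIP and 0.50 in input. The local rate was never set below the genome-wide ChIP rate, which is above the average rate of X. Fewer tags and this stricter rate favour fewer calls on X, and no rescaled count was made for it. The low value for X is therefore not a measure of how sites are distributed. The ChIP share of tags over the input share was 1.04 on chromosome 8 and 0.938 on X, and it ran from 0.931 on chromosome 13 to 1.04 on chromosome 1 among the 19 autosomes.

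The excess of regions on chromosome 8 coincided with a change in the ChIP to input ratio along that chromosome. Between 53 and 111 Mb the median log2 ratio of 57 bins of 1 Mb was 0.41, and in the other 69 bins it was -0.17. Of the 103 regions, 80 lay in that stretch (1.48 per covered Mb, 95% exact Poisson interval 1.17 to 1.84). When the input rate inside the stretch was raised by its own ratio, an alternative chosen after seeing the data, 36 regions remained there (0.664 per covered Mb, 0.465 to 0.920) and the whole of chromosome 8 carried 59 (0.491, 0.373 to 0.633). Both intervals include 0.474, the genome-wide rate before rescaling. Rescaling lowered the number of regions over the genome from 1147 to 1103, over 2418.85 covered Mb. The genome-wide rate after rescaling thus lies just below 0.465, the lower limit for the stretch, and inside the interval for the whole chromosome. The rest of chromosome 8 carried 0.348 per covered Mb (0.221 to 0.522). Raising the input rate can only remove regions, so the direction of this change was fixed in advance. Stretches with a ratio below the autosome median were not rescaled. How much of the excess came with the change in ratio is therefore not settled. On chromosome 6, the ratio between 72 and 84 Mb was lower, with a median log2 of -0.82 in 12 bins against 0.06 in the rest of the chromosome, and 1 enriched region lay there. These stretches were picked after their values were seen and were not the only ones: of 60 stretches, 13 on 9 chromosomes differed from the autosome median by at least 0.2 (log2), 1 above it and 12 below. The largest differences after that on chromosome 6 were on chromosome 13 from 61 to 69 Mb (-0.60) and chromosome 4 from 143 to 148 Mb (-0.43), in 7 and 5 bins. The spread of single 1 Mb bins around their neighbours, genome-wide, was 0.089 on the log2 scale.

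**Figure D4:**
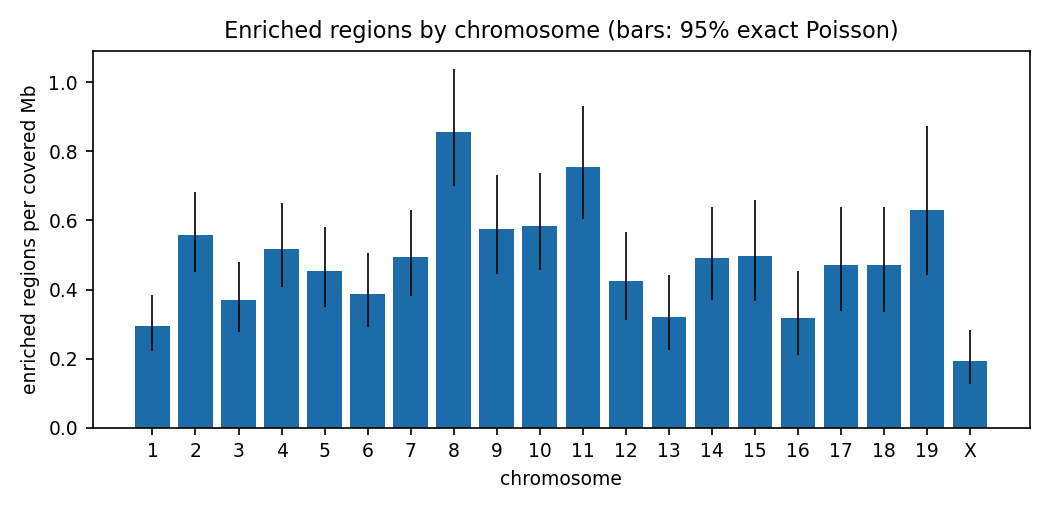
Enriched regions per covered Mb (vertical axis, bars from 0) by chromosome, with 95% exact Poisson intervals, from 1 ChIP and 1 input library. Chromosome 8 is highest at 0.856 and X lowest at 0.192 per Mb, where sparse tags were tested against a rate not below the genome-wide one. The value for 8 falls to 0.491 when its 53 to 111 Mb stretch is scaled to its own ratio.

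**Figure D5:**
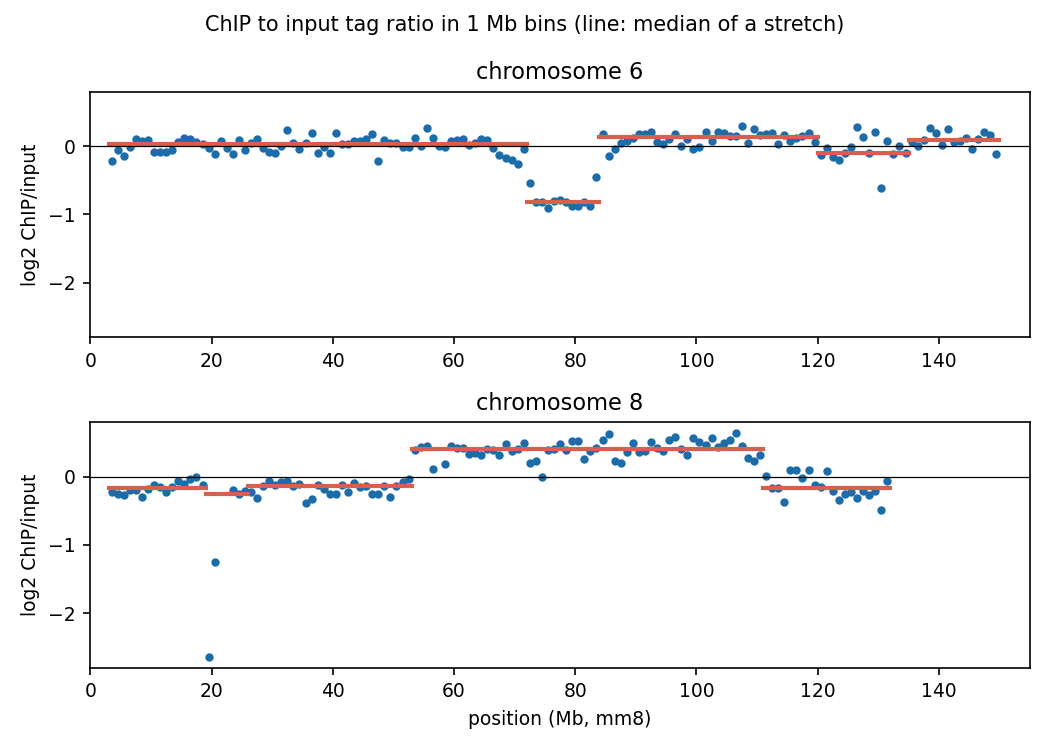
Log2 ratio of ChIP to scaled input tags in 1 Mb bins (points) along chromosomes 6 and 8, with the median of each stretch as a line, against position in Mb (mm8). The ratio drops to -0.82 from 72 to 84 Mb on chromosome 6 and rises to 0.41 from 53 to 111 Mb on chromosome 8.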

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

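Both results here came from tags outside the scanned chromosomes and were noticed after the data were seen. The ChIP library held 1909 tags on chromosome Y, of which 974 lay on the plus and 935 on the minus strand. It held 2504 distinct tags on the mitochondrial chromosome M, of which 931 lay on the plus and 1573 on the minus strand. They stood out as tags in a part of the data that the comparison did not use. The input tags analysed here cover neither chromosome, so there is no background level to set them against and no enrichment was computed.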

How the results depend on the processing

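Leaving out input pile-ups, regions short of tags on a strand or the X region, rescaling chromosome 8 and not moving tags were chosen after seeing the data. The number of regions, 1147, lay between 917 and 1313 under 13 of 18 alternatives, but the regions turned over: of the 1147, 727 were overlapped with windows of 600 bp, 868 with 200 bp and 821 with tags not moved. The number was 6580 with the genome-wide rate alone, 1774 with input in 10 kb and the genome-wide rate, 748 at an adjusted p under 0.01, and 412 and 414 in random subsets of the ChIP tags; a lower local rate, a stricter threshold or fewer tags is what these settings consist of. All 20 named regions were called in 15 of 18 settings, and 18 in the others. Because the 20 were chosen for the smallest adjusted p in the same tags, most settings could hardly lose them. The count is therefore not a test of them. The exceptions were the 2 at input pile-ups, on chromosomes 9 and 2. They fell short of 5 times the local rate, at 4.40 and 3.09, were left out with the pile-ups, and reversed to 0.281 and 0.0662 with all tags kept, where input repeats count and ChIP repeats, collapsed before deposit, cannot. The share of ChIP tags in regions, 0.317%, left its counting interval under all 8 alternatives run: 0.283% with all tags kept, 0.304% with windows of 600 bp, 0.311% with input scaled by the median ratio over 10 kb bins, 0.253% at an adjusted p under 0.01, 0.241% with at least 5 times the local rate, 0.241% without pile-ups, 0.312% without the X region and 0.310% with chromosome 8 rescaled. With all tags kept, the input's normalised strand coefficient was 4.56, which put it above the ChIP value of 2.87, and its relative one 0.0813; the cause was not tested. The ChIP to input ratio was then 1.10 for chromosome 8 and 0.953 for X, and 19 of 20 chromosomes left their intervals; 431281 of 664851 repeated input tags lay on chromosomes 2 and 14. Coefficients were called moved at a change of 10%. Start-site, gene-list and motif alternatives were not run. Depth limits weak sites: 25 of 50 simulated regions with 8 extra tags were found.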

Other observations

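The tests of chromosome 8 by removal of tags near regions and by bins with fewer input tags, and those of chromosome 6 in 10 kb bins, were set out before their results were seen but after the steps themselves had been noticed; all others in this part were chosen after. A small share of regions had close neighbours, though more than random placement gave. Of the 1094 regions with few input tags, 42 (3.84%) had another within 10 kb, against a mean of 12.3 (range 2 to 28) in 100 random placements of as many positions per chromosome on input tags. Some of these may be single sites split in the merging of windows; with positions within 1 kb of each other joined first, in the random placements too, 37 of 1090 had a neighbour, against a mean of 11.8 (range 2 to 28). No list of genes was compared with these positions.

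The ChIP to input ratio changed in long steps on several chromosomes, and for those on 8 and 6, the only ones tested and picked after their values were seen, a copy number difference between the cells of the 2 libraries is a candidate explanation. On chromosome 8 the stretch stood 0.58 (log2) above the rest of the chromosome but 0.38 above the autosome median, since the rest, where input density was 1.20 times the autosome median, lay below it. After removal of all tags within 5 kb of a region the step was 0.57, so tags near called regions did not carry it. The removal cannot decide on weaker or broader Tbx3 binding. All called regions together held only 0.317% of ChIP tags, and sites below the threshold were kept. Loss of non-unique ChIP tags is argued against by the ChIP density inside, 1.45 times the autosome median. The 95th percentile in other autosomal bins was 1.20. A copy number difference needs the step in bins with fewer input tags too, where it was 0.62, though choosing bins by their input count can itself raise the ratio, and an even drop on chromosome 6, where the relative width of the middle of 10 kb bins was 1.23 times that of the rest. On chromosome 6 loss of non-unique tags stays open. In the stretch 17.4% of 10 kb bins had a ratio of 0.8 or more, between the limits of 10% and 25% set for the test. The share was 80.1% in the rest of the chromosome. ChIP density in the stretch was 0.446 of the autosome median, so counting noise in 10 kb bins can also carry bins over 0.8. The test therefore cannot tell patchy loss from an even drop. Which cell line gave each library is not given in the labels.

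The region of most tags with few input tags, on chromosome X, may have another origin than the other sites. Its 300 ChIP tags lay within 490 bp, with 4 tags in 1 kb on either side together, and its top window held 216 tags against 79 in the next such region. Extra copies in the genome of the cells of both libraries are argued against by the input, which had 3 tags in the top window (upper 95% limit 8.77) where 10 times the local rate would be 19.1, and copies in the cells of the ChIP library alone stay open. Protein-bound fragments stay open: the strand offset of 29 bp lay below 35.25 bp, the 5th percentile of 118 other regions with few input tags and at least 20 ChIP tags, all called on unmoved tags, which favours offsets near 0, but its resampling interval of -13 to 83 bp reached above it.

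The 2806 regions where input exceeded ChIP are consistent with loss of ChIP tags in repeated sequence, if only unique hits were kept for that library: 60.5% of them held under 25% of the genome-wide ChIP rate. They were called for a low ChIP count, which favours that outcome. Their number also depended on input depth, with 1826 called from thinned input. The 2806 were also clustered, 1812 (64.6%) having another within 10 kb against a mean of 112.78 in random placements. Accessible chromatin sheared more often in the input stays open, since 37.5% of the regions held at least 50% of the ChIP rate.

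The input was denser on chromosome 8 than on any other autosome, at 1.18 times the autosome median, with chromosome 11 next at 1.09. ChIP density was highest on chromosome 8 as well, at 1.23 times its autosome median. The part of chromosome 11 from 3 to 8 Mb was also examined for a step. It had a ChIP density of 1.17 and an input density of 1.30 times the autosome median, against 1.11 and 1.13 in the rest of that chromosome. Segmentation kept chromosome 11 as 1 stretch from 3 to 122 Mb, so it placed no step there.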
